A study of Mus musculus with 24 samples.

How the data were processed

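The series holds 24 RNA sequencing libraries of LSK cells sorted by flow cytometry from leg and hip bone marrow of 21-day-old mouse pups after depletion of lineage-positive cells. Per the labels, RNA with an integrity number above 8.0 went into a low-input polyA library kit, which does not mark strand. Sex and maternal diet define 4 groups of 6 libraries, and the labels place 2 libraries of each group in each of 3 batches. Groups, replicate numbers and batches were taken from the labels alone.

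The deposited files give raw counts per gene, 1 file per library. Per the submitters' processing notes, FastQC, cutadapt, STAR, HTSeq and the mouse build GRCm39 were used, and DESeq2 is also named. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. Because the kit does not mark strand, reads of overlapping antisense genes such as Xist and Tsix cannot be told apart, and genes with near-identical copies can exchange or lose reads.

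Every file listed 55414 gene identifiers, of which 52081 matched a symbol in the reference annotation and 3333 did not. That annotation is of an older mouse build than the files, so it served only for names, chromosomes and gene types, and no coordinates are given. HTSeq's closing lines, which name no gene, held 31.0 to 39.3% of each library's total (median 34.8%) and stayed out of library sizes and tests. Libraries had 38057263 to 51581968 counts in genes. Counts of any pair of libraries differed by at least 18.6 times sampling noise (chi-square per degree of freedom), so the spread between libraries exceeded counting error.

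Counts were tested in edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr, which left 19616, libraries were scaled by TMM (factors 0.932 to 1.05), and a robust quasi-likelihood model with a term for each group and for batch was fitted to all 24 libraries. The common biological coefficient of variation was 0.261. The 6 comparisons were maternal diet in females, in males and averaged over both, the male minus female difference of the diet effects, and sex in control and in Western-diet pups. P-values were adjusted by Benjamini-Hochberg within a comparison and called under 0.05, and the standard error of a log2 fold change was its size divided by the root of the F statistic. CPM are counts scaled to library sizes corrected by TMM. All p-values are two-sided.

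For gene groups, 34 lists of genes were fixed, covering stem cell and lineage priming programs, markers of other cells a sort can hold, cell cycle, metabolism, stress and immune responses, and sex-linked genes. Of their 870 symbols 869 matched the files. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over lists, with camera at an estimated correlation, and with fry. With an estimated correlation, camera's calls that held were the megakaryocyte-erythroid list in females, the mature erythroid list in males, both of these in the average, and the Y-linked and X-linked lists in each sex comparison. Genes were named by a fixed rule. Among called genes with a proper symbol and one direction in all 3 batches, it takes the 12 higher and 12 lower genes with the smallest p in each within-sex diet comparison and the 6 and 6 in the other 4, filled up to 5 by the smallest p where fewer than 5 passed. It adds up to 4 members of every list that was called or had a member called over the list alone, the sex-linked genes, the markers Kit, Ly6a, Flt3, Slamf1, Procr, Mpo and Dntt, and the most abundant gene of each list of another cell type. Not every gene the rule takes is described, and some are not reported here.

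The model, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. These alternatives were another normalization, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, no batch term, the replicate number as a block, only the 2 groups compared, each batch left out and each library left out. After the data were seen, 3 more were added: leaving out both female control libraries of batch 3, and the share of reads in no feature or the globin level as a covariate. The permutation tests of list scores, globin genes and library measures within sex and batch were also added then. A list score is the mean over its genes of log2 CPM centred per gene.

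The fit was tested on simulated counts drawn from the real means and library sizes, with 50 of 19616 genes changed at each fold. In the female diet comparison 16% of genes changed 1.5-fold, 56% changed 2-fold and 82% changed 3-fold were recovered, in the male one 20, 52 and 82%, and in the sex comparison of controls 18, 54 and 82%, with 1 false call in each. The simulated counts had no batch shift, correlation between genes or outlying library, so the false calls need not carry over. Other groupings of the real libraries within batch called up to 580 genes for diet in females, with a median of 0. Groupings that move few libraries keep part of the real contrast, so these calls need not be false. Tables were joined in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Splicing, allele-specific expression and genome coordinates were not analysed here.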

Results

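Bone marrow LSK cells of mouse pups were profiled by RNA sequencing. LSK cells are negative for lineage markers and positive for Sca-1 and Kit, and they hold the hematopoietic stem cells and multipotent progenitors. The pups were 21 days old, and their C57BL/6J mothers had eaten regular chow (control) or a Western diet, given to induce maternal obesity, from before mating until the end of lactation. Sex and maternal diet gave 4 groups of 6 libraries, spread over 3 labelled batches with 2 libraries of every group in each. The labels name neither dams nor litters, so p-values measure the spread between these libraries, and littermates may not be independent of each other. The comparisons ask what maternal diet changed in female and in male pups, and whether it did so differently in the sexes.

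Depth was even over the groups. The 24 libraries held 38057263 to 51581968 counts in genes, and counts were detected for 25673 to 27858 genes per library. Log2 expression correlated between libraries of one group at r = 0.952 or more, with a median of 0.978. No library repeated another, since the counts of every pair differed by far more than sampling noise (the lowest chi-square per degree of freedom was 18.6). The first principal component held 17.5% of the variance, and batch accounted for a share of 0.505 of it. Female control libraries 5 and 6, both of batch 3, stood apart on it at -91.0 and -72.4.

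**Figure D1:**
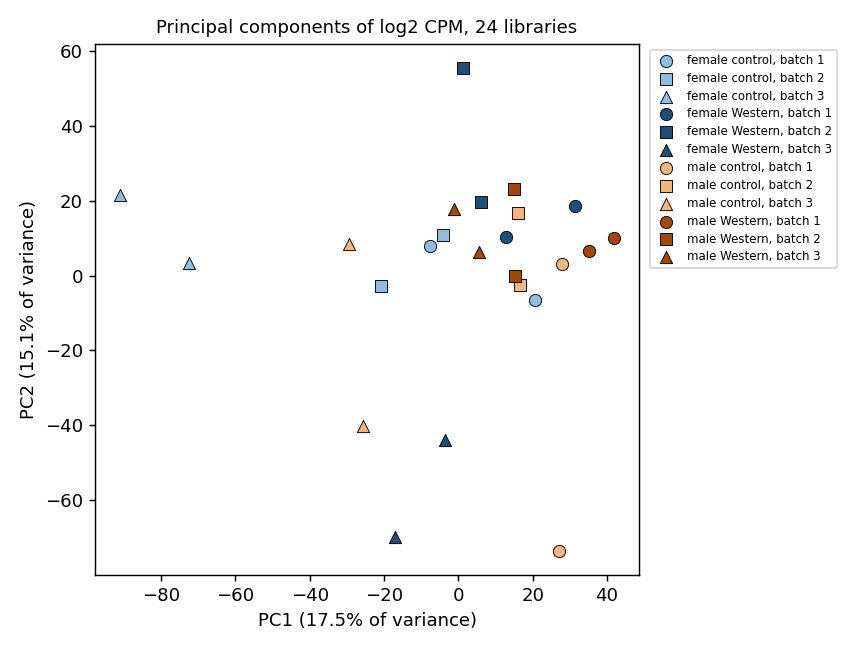
Position of each of the 24 libraries on the first principal component (x axis, 17.5% of the variance) and the second (y axis, 15.1%) of log2 CPM. Colour marks sex and maternal diet and shape marks the batch; the female control libraries of batch 3 lie at -91.0 and -72.4 on the x axis.

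Sex-linked transcripts matched the labelled sex in all 24 libraries. Xist, the RNA that silences one X chromosome in females (chromosome X), had 9344 to 27505 counts in female libraries and 8 to 45 in male ones. Ddx3y, a helicase gene of the Y chromosome, had at least 5165 counts in male libraries and at most 12 in female ones, and Eif2s3y, Kdm5d and Uty separated the sexes in the same way.

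In female pups, maternal Western diet lowered genes of the erythroid lineage. Car1, a carbonic anhydrase abundant in erythroid progenitors (ENSMUSG00000027556, chromosome 3), fell from 696 ± 255 CPM in control females to 256 ± 121 CPM in Western-diet females (mean ± SD, n = 6 per group), 2.83-fold lower, and every Western-diet library lay below every control library. Epor, the erythropoietin receptor (chromosome 9), fell 2.21-fold from 104 ± 42.6 to 44.9 ± 9.40 CPM, again with no overlap between the groups. The red cell membrane genes Rhag and Ermap fell 3.08-fold and 2.63-fold, with 5 of 6 Western-diet libraries below all controls. Tspo2, which is expressed in late erythroid cells, fell 2.51-fold. Adjusted p-values of these genes from edgeR's quasi-likelihood test lay between 7.33e-06 for Car1 and 0.000190 for Rhag.

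The fixed lists gave the same picture, though the megakaryocyte-erythroid priming list itself holds Car1, Epor, Rhag and Ermap. Of 26 tested genes of the megakaryocyte-erythroid priming list, 12 fell and 1 rose in females over all genes tested (14 and 1 adjusted over the list alone), with a median log2 fold change of -0.57. The list was called by camera at an adjusted p of 2.48e-14, and the call held at adjusted p = 0.0273 with an estimated correlation. The erythroid transcription factors Gata1 (-1.0) and Klf1 (-1.33) were among the genes that fell, and Fli1, a factor of megakaryocyte development, was the member that rose (0.46); these 3 were chosen after their values were seen. Of 11 genes of the mature erythroid list, which marks later red cell precursors that the sort should remove, 6 fell (7 adjusted over the list alone), among them Slc4a1 (log2 fold change -1.73) and Epb42 (-1.08). That list had a median of -0.82 and an adjusted p of 4.48e-10 by camera (adjusted p = 0.0575 with an estimated correlation). In an exact permutation test of list scores within batch, added after the data were seen, the scores of these lists differed by -0.60 and -0.89, both at p = 0.00926. That is the smallest that 216 redraws give, and neither passed after adjustment over 34 lists (permutation p = 0.157 adjusted). The beta globin Hbb-bs stood at 693 ± 318 CPM in Western-diet and 1279 ± 1316 CPM in control females (log2 fold change -0.53, adjusted p = 0.543, edgeR), and the adult globin genes share reads with near copies.

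Other genes with large falls in females were outside these lists. Slc30a10, a manganese exporter, fell from 7.71 ± 4.25 to 1.31 ± 0.577 CPM (n = 6), which was 5.64-fold and held without overlap. Tspan33 fell 2.88-fold, Hpn 2.56-fold, Col5a1 2.39-fold, Slc25a21 2.34-fold, Sphk1, a kinase that makes sphingosine 1-phosphate, 2.32-fold, Mgll, which releases fatty acids from monoacylglycerols, 2.29-fold, and Cela1 2.00-fold. Each was lower than the control mean in 6 of 6 libraries, and edgeR's adjusted p-values were at most 0.000123. Asns, the asparagine synthetase, fell 1.88-fold (adjusted p = 0.000785, edgeR), and Sesn2, like Asns a target of the integrated stress response, fell 1.97-fold. Of 30 antioxidant response genes 3 fell, namely Nqo1 (-0.71), Prdx3 (-0.40) and Gpx4 (-0.34), and 8 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.00869, adjusted p = 0.506 with an estimated correlation; exact permutation p = 0.0278, 0.157 adjusted over 34 lists). Of 20 glucocorticoid response genes Fkbp5 rose (0.82), and Nfkbia (-0.57) and the metallothionein Mt1 (-0.96) fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.422).

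Some genes of the stem cell and granulocyte-monocyte lists rose in Western-diet females. Of 23 granulocyte-monocyte priming genes 4 rose and none fell (6 and 0 adjusted over the list alone): Nkg7 from 180 ± 64.9 to 305 ± 51.3 CPM (mean ± SD, n = 6), Gfi1, a repressor needed for granulocyte development, 1.87-fold, Anxa3 1.82-fold and Csf2rb, a receptor chain for GM-CSF and IL-3, by 0.59 on the log2 scale. The median of the list was 0.60 (camera adjusted p = 2.21e-06, adjusted p = 0.506 with an estimated correlation), while Mpo, its most abundant gene, did not pass (3631 ± 2075 against 2375 ± 822 CPM, log2 fold change 0.60, edgeR adjusted p = 0.261). Of 35 stem cell genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), with Mecom 1.46-fold, Meis1 1.43-fold, Angpt1 1.56-fold and Ifitm1 2.00-fold higher and Mllt3, chosen after its value was seen, at -0.43 (median 0.28, camera adjusted p = 0.00253, adjusted p = 0.560 with an estimated correlation). Of 15 Hox and Meis factors, regulators of progenitor self-renewal, 3 rose, among them Meis1 and Hoxa7 (1.43-fold) (4 and 0 adjusted over the list alone; camera adjusted p = 0.00530, adjusted p = 0.506 with an estimated correlation). Outside the lists, Iqcg rose 2.63-fold from 1.06 ± 0.269 to 2.79 ± 0.585 CPM and the protease inhibitor gene Serpina3g, of a family with near-identical members, rose 2.30-fold from 32.9 ± 10.7 to 72.3 ± 16.9 CPM, both without overlap. In the exact permutation test within batch the granulocyte-monocyte score differed by 0.50 (p = 0.0185, 0.157 adjusted over 34 lists). The Hox and Meis score differed by 0.26 (exact permutation p = 0.0370, 0.180 adjusted) and the stem cell score by 0.21 (p = 0.0833, 0.202 adjusted). B4galt6 rose 1.94-fold, Galk2 1.91-fold, Rai14 1.86-fold and Csgalnact1 1.71-fold.

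Some interferon response and B cell genes also rose in these females, and camera called their lists higher at the preset correlation alone. Of 42 type I interferon response genes 5 rose (12 rose and 1 fell adjusted over the list alone): Oas2 2.08-fold, Oas1a 1.89-fold, Trim30a 1.74-fold, the RNA sensor Ddx58 1.45-fold and Parp14, chosen after its value was seen, at 0.47 on the log2 scale. The Oas and Trim30 genes belong to families that can share reads. The median of the list was 0.50 (camera adjusted p = 9.63e-07, adjusted p = 0.683 with an estimated correlation). No gene of the interferon gamma and antigen presentation list passed edgeR's test over all genes or over the list alone, although its median was 0.45 (camera adjusted p = 6.73e-05, adjusted p = 0.683 with an estimated correlation). Of 15 B cell genes 3 rose (5 adjusted over the list alone): the antibody genes Igkc, 3.11-fold, and Jchain, 2.83-fold, and the receptor chain Cd79b, 1.41-fold (median 0.45, camera adjusted p = 0.00120, adjusted p = 0.506 with an estimated correlation). In the exact permutation test within batch the type I interferon score differed by 0.43 (p = 0.148, 0.296 adjusted over 34 lists). The interferon gamma score differed by 0.41 (exact permutation p = 0.0833, 0.202 adjusted) and the B cell score by 0.44 (p = 0.0463, 0.197 adjusted). By batch, the score of the type I interferon list was 0.21, -0.07 and 1.15 higher in Western-diet females in batches 1, 2 and 3, that of the interferon gamma list 0.03, 0.09 and 1.11, and that of the B cell list 0.32, 0.28 and 0.73. With batch 3 left out, camera's adjusted p was 0.370 for the type I interferon and 0.558 for the interferon gamma list.

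In all, 432 genes rose and 632 fell in females among 19616 tested at an adjusted p under 0.05 (edgeR quasi-likelihood test on 24 libraries with batch as a term), and 1034 of these 1064 genes had one direction in all 3 batches. Genes chosen over all libraries tend to keep their sign in parts of them, so such agreement is no separate replication. Within batches 1, 2 and 3, with 2 libraries per group each, the count was 6, 142 and 3788. It fell to 535 without female control library 5, to 504 without female control library 6, to 575 without female Western-diet library 5, and to 154 (10 higher and 144 lower) without both female control libraries of batch 3. All 1064 genes kept their direction without that pair, and 153 of them stayed past the threshold. Car1, Tspo2, Rhag, Ermap, Epor, Slc30a10, Tspan33, Hpn, Col5a1, Mgll, Cela1, Rai14 and Iqcg passed in every setting tried, whereas no gene named here from the interferon, B cell, stem cell, Hox and granulocyte-monocyte lists passed without that pair, and neither did Klf1, Fli1, Slc4a1, Epb42, Sesn2, Nqo1, Prdx3, Gpx4, Fkbp5 or Galk2.

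**Figure D2:**
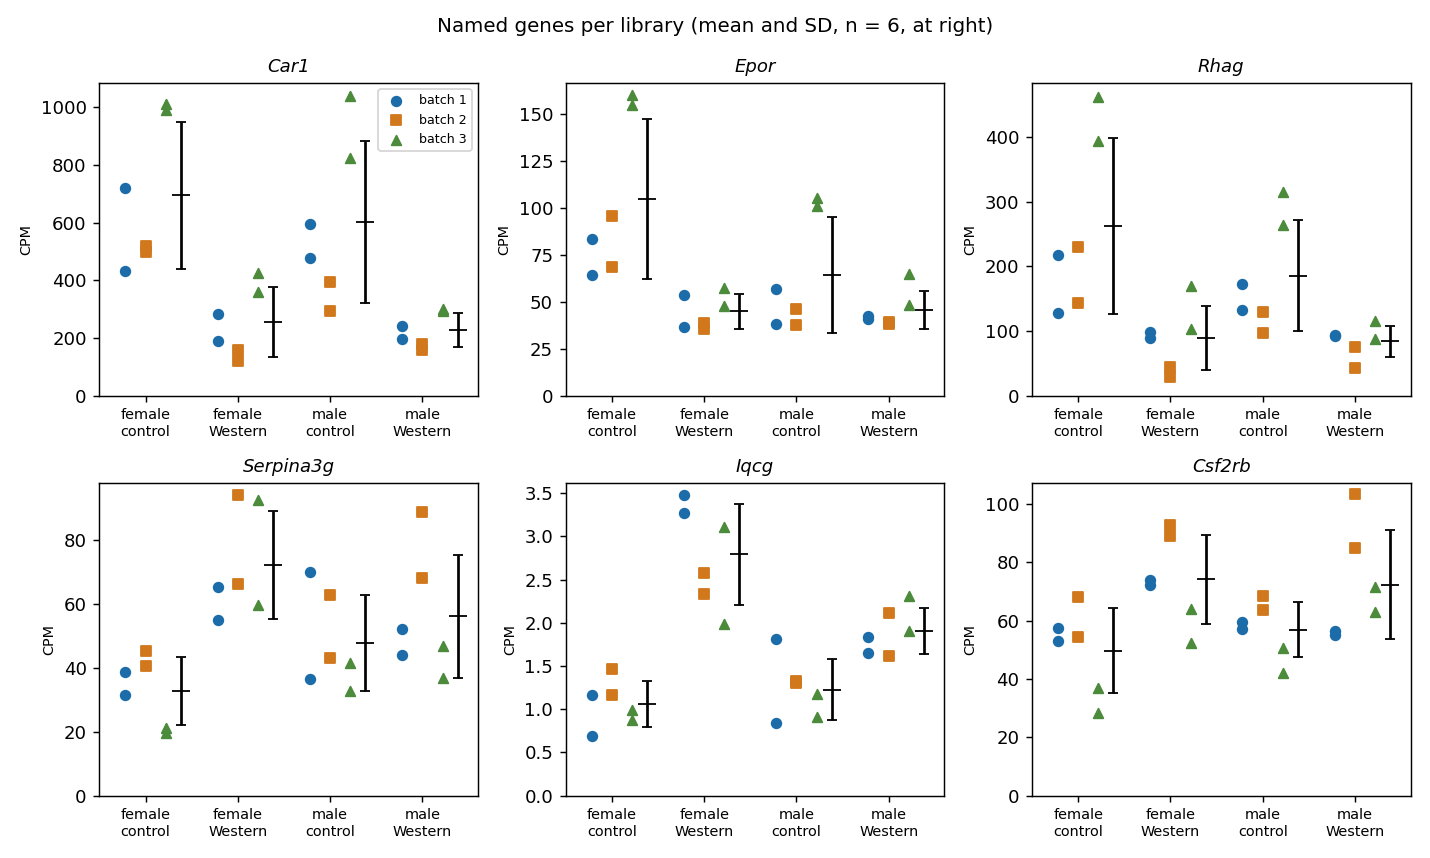
CPM (y axis) of Car1, Epor, Rhag, Serpina3g, Iqcg and Csf2rb in each library, by group (x axis); colour and shape mark the batch, and the bars at right give the mean and SD of 6 libraries. Car1 averaged 696 CPM in control and 256 CPM in Western-diet females, and 604 and 228 CPM in control and Western-diet males.

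In male pups, the genes that fell with maternal Western diet were Car1 and Aldh1a7. Car1 fell from 604 ± 281 to 228 ± 60.3 CPM (mean ± SD, n = 6 per group), 2.50-fold lower (log2 fold change -1.32 ± 0.15 SE, adjusted p = 7.24e-05, edgeR quasi-likelihood test). Aldh1a7, an aldehyde dehydrogenase (chromosome 19), fell from 9.93 ± 5.05 to 4.42 ± 1.23 CPM, 2.10-fold lower (adjusted p = 0.0183, edgeR). Each was below the control mean in 6 of 6 libraries. Rhag had a lower value but did not pass, with a log2 fold change of -1.04.

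Camera called the mature erythroid list, which marks cells the sort should remove, lower in males. None of its 11 genes passed over all genes tested, 10 fell adjusted over the list alone, and the median log2 fold change was -1.19 (camera adjusted p = 1.91e-22, adjusted p = 0.00247 with an estimated correlation). Its red cell transcripts included the globins. Hbb-bs stood at 776 ± 405 CPM in Western-diet and 2004 ± 1059 CPM in control males (log2 fold change -1.34, edgeR adjusted p = 0.357). On log2 CPM Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 were each lower by an exact permutation test within batch (p = 0.00926, the smallest that 216 redraws gave). Adjusted over 6 genes, these globins with Ly6a and Kit, the permutation p was 0.0139. That test was added after the data were seen, and the globins share reads, so they do not count as separate results. Of 26 megakaryocyte-erythroid priming genes Car1 fell (8 fell adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.30e-08, adjusted p = 0.107 with an estimated correlation). Camera also called the G1/S cell cycle genes lower (median -0.21, 34 of 35 negative, adjusted p = 2.70e-11, adjusted p = 0.218 with an estimated correlation) and the granulocyte-monocyte genes higher (median 0.33, 23 of 23 positive, adjusted p = 1.95e-05, adjusted p = 0.448 with an estimated correlation), with no member of either past edgeR's test. In the exact permutation test within batch the score differed by -1.08 for mature erythroid and -0.20 for G1/S genes (both p = 0.00926, 0.157 adjusted over 34 lists). It differed by -0.29 for megakaryocyte-erythroid genes (exact permutation p = 0.0185, 0.210 adjusted) and by 0.38 for granulocyte-monocyte genes (p = 0.0648, 0.275 adjusted). Camera called 7 further lists lower in males, with no member past edgeR's test over all genes. The medians were -0.31 for T, NK and innate lymphoid genes (adjusted p = 0.000559, adjusted p = 0.644 with an estimated correlation) and -0.23 for dendritic cell and macrophage genes (0.0106, adjusted p = 0.777 with an estimated correlation). They were -0.21 for B cell genes (adjusted p = 0.0458, adjusted p = 0.777 with an estimated correlation) and -0.19 for interferon gamma genes (0.0106, adjusted p = 0.977 with an estimated correlation). They were -0.17 for antioxidant genes (0.000113, adjusted p = 0.256 with an estimated correlation), -0.16 for cholesterol genes (0.000161, adjusted p = 0.629 with an estimated correlation) and -0.06 for oxidative phosphorylation genes (0.00948, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone, 2 antioxidant and 2 cholesterol genes were lower and 0 of the other 5 lists. In the exact permutation test within batch the smallest p of these 7 was 0.0278 for antioxidant genes (0.236 adjusted), with 0.0648 for T, NK and innate lymphoid, 0.222 for B cell and 0.528 for interferon gamma genes. The lipid genes Cpt1a (0.49), Scd2 (0.66) and Abca1 (0.68) had higher values in males without passing (edgeR adjusted p = 0.0617, 0.101 and 0.249).

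These 2 genes stood beside 1657 at an unadjusted p under 0.05 in edgeR's test, 99 called by DESeq2 and 132 by limma-voom. Within batches 1, 2 and 3 the count was 2, 0 and 58. The count was 1 without male control library 3 or 6 or male Western-diet library 3, 5 or 6, 4 without female Western-diet library 3 or male Western-diet library 2, 7 without male control library 4 and 13 without male Western-diet library 4. Car1 lost its call with batch 3 left out and with no batch term. Aldh1a7 lost its call in 12 of 38 other settings: with any batch left out, no batch term, the replicate block, only the 2 groups compared, the globin level as covariate, and each of the 5 libraries without which the count was 1.

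Averaged over both sexes, both erythroid lists were lower with maternal Western diet. The mature erythroid list marks red cell precursors that the sort should remove. Whether the sorts of the 2 diets held different numbers of such cells was not tested. Of the 11 mature erythroid genes 9 fell (11 adjusted over the list alone), with a median log2 fold change of -1.0 (camera adjusted p = 9.51e-21, adjusted p = 0.00378 with an estimated correlation). Of the 26 megakaryocyte-erythroid genes 12 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 4.54e-17, adjusted p = 0.00592 with an estimated correlation). Car1 fell 2.66-fold (log2 fold change -1.41 ± 0.10 SE, edgeR adjusted p = 2.08e-08), Rhag 2.52-fold and Aldh1a7 2.20-fold. The scores of both lists were lower in Western-diet pups of each sex in every batch. For the megakaryocyte-erythroid list the differences in batches 1, 2 and 3 were -0.26, -0.63 and -0.91 in females and -0.17, -0.12 and -0.58 in males, and for the mature erythroid list -0.96, -1.13 and -0.59 in females and -0.85, -1.10 and -1.29 in males. By a permutation test of these scores within sex and batch, added after the data were seen, the mature erythroid score differed by -0.99 (p = 4.29e-05, 0.00146 adjusted over 34 lists) and the megakaryocyte-erythroid score by -0.44 (p = 8.57e-05, 0.00146 adjusted) with n = 12 per diet and 46656 redraws.

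**Figure D3:**
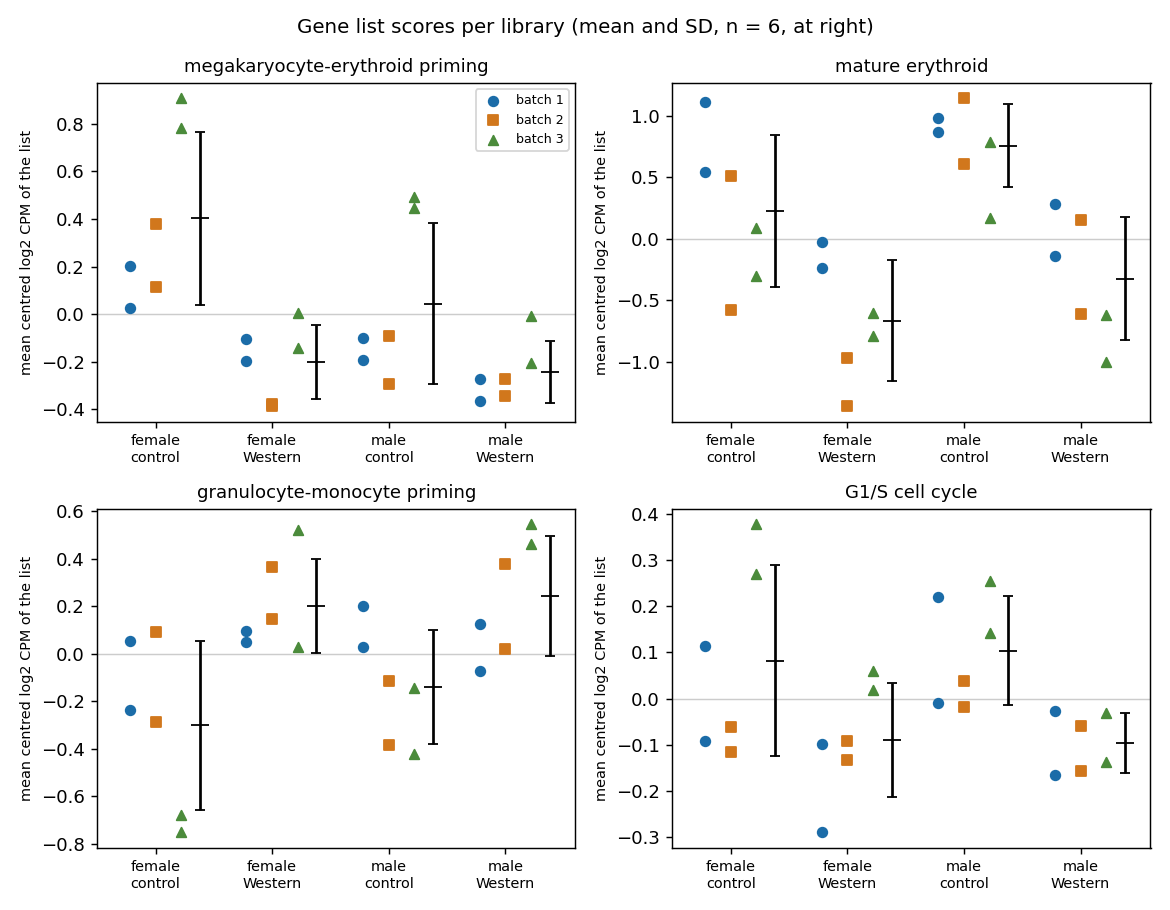
Score of 4 gene lists in each library (y axis, mean over the list of log2 CPM centred per gene), by group (x axis); colour and shape mark the batch, and the bars at right give the mean and SD of 6 libraries. The mature erythroid score averaged 0.76 in control and -0.32 in Western-diet males, and 0.23 and -0.66 in control and Western-diet females.

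Some lipid-handling genes rose and others fell in the average, and neither fatty acid list was called. Of 25 fatty acid synthesis and LXR target genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.50, 2.70e-07 by fry for either direction). Of 35 fatty acid oxidation genes 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.407, 3.42e-06 by fry). Fry's test does not compare a list with other genes. In the average 4039 of 19616 genes had an unadjusted p under 0.05 in edgeR's test. Cpt1a, which admits long-chain fatty acids to mitochondria, rose (log2 fold change 0.38 ± 0.07 SE, edgeR adjusted p = 0.00110), the desaturase Scd2 1.43-fold (0.00249), and the cholesterol exporters Abca1 and Abcg1, targets of the sterol sensor LXR, 1.47-fold (0.0133) and 1.73-fold (0.0120). Acsl1, which activates long-chain fatty acids, fell 1.37-fold (edgeR adjusted p = 0.000354). The carnitine acetyltransferase gene Crat (-0.58), Acaa2 (-0.29), Acsl5 (-0.27), Elovl1 (-0.27) and Lpin1 (-0.51) fell too. Lpin1, Acsl5 and the desaturase Scd1, the remaining gene that rose (0.52), were chosen after their values were seen. The call of Scd1 ended in 27 of 37 other settings and that of Lpin1 in 23, among them 20 and 17 of the 24 with a single library left out. The calls of Abca1 and Abcg1 ended with the globin level as covariate. Of 26 cholesterol biosynthesis genes Fdft1 (-0.50) and Idi1 (-0.37) fell (9 fell and 1 rose adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.000194, adjusted p = 0.641 with an estimated correlation). Their score differed by -0.18 in the permutation test within sex and batch (p = 0.00669, 0.0325 adjusted over 34 lists). In batches 1, 2 and 3 it differed by -0.02, -0.39 and -0.24 in females and by -0.33, 0.06 and -0.17 in males. As small a camera p came from 13 of 100 splits of the libraries within sex and batch, the real one included.

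G1/S and antioxidant genes were lower and granulocyte-monocyte priming genes higher in the average. Of 35 G1/S genes 6 fell (10 adjusted over the list alone), led by the replication licensing factor Cdc6 (-0.47), with a median of -0.16 (camera adjusted p = 4.42e-08, adjusted p = 0.293 with an estimated correlation). Their score differed by -0.19 in the permutation test (p = 0.000171, 0.00194 adjusted over 34 lists), with differences in batches 1, 2 and 3 of -0.20, -0.02 and -0.29 in females and -0.20, -0.12 and -0.28 in males. Of 30 antioxidant genes 7 fell (12 fell and 2 rose adjusted over the list alone), with Nqo1 1.54-fold and the mitochondrial peroxidase Prdx3 1.33-fold lower (camera adjusted p = 0.000150, adjusted p = 0.270 with an estimated correlation; permutation p = 0.000729, 0.00619 adjusted). The antioxidant score differed in batches 1, 2 and 3 by -0.17, -0.28 and -0.001 in females and by -0.12, -0.09 and -0.20 in males. Of 23 granulocyte-monocyte genes 5 rose (10 adjusted over the list alone), namely Nkg7, Gfi1, Csf2rb, Anxa3 and, chosen after its value was seen, Cebpa (0.75). That list had a median of 0.43 (camera adjusted p = 2.58e-08, adjusted p = 0.270 with an estimated correlation). Its score differed at a permutation p of 0.00146 (0.00991 adjusted), by 0.17, 0.35 and 0.99 in females and -0.09, 0.45 and 0.79 in males in batches 1, 2 and 3. As small a camera p came from 8 of 100 splits of the libraries within sex and batch, the real one included. For the G1/S and the antioxidant list it came from 4 of 100 each. Adjusted over 34 lists these shares were 0.453 for granulocyte-monocyte genes and 0.272 for the other lists. The Hox and Meis score was higher by 0.23 (permutation p = 0.00214, 0.0121 adjusted), with 2 genes called, among them Hoxa7, and adjusted p = 0.293 with an estimated correlation. Camera also called the stem cell (median 0.19, adjusted p = 0.0199) and type I interferon lists (0.19, 0.00894) higher and the G2/M (-0.09, 0.00428) and oxidative phosphorylation lists (-0.05, 0.0381) lower. Each had an adjusted p = 0.747 with an estimated correlation. Among the genes that rose most clearly were Mcf2 on chromosome X (2.48-fold, edgeR adjusted p = 0.000341), Iqcg (2.03-fold) and Socs2, a brake on cytokine signalling (1.66-fold).

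The average held 1118 genes, 429 higher and 689 lower (edgeR quasi-likelihood test), 1105 of them with one direction in all 3 batches. That agreement too is favoured by choosing the genes in the same libraries. Within batches 1, 2 and 3 the count was 5, 49 and 2685. It was 736 without female control library 6, 716 without male Western-diet library 5, 744 without male Western-diet library 6 and 447 without both female control libraries of batch 3. Without batch 3 the calls of Cdc6, Csf2rb, Nqo1, Prdx3, Gfi1, Nkg7, Anxa3, Cebpa, Hoxa7, Scd1, Scd2, Abcg1, Fdft1, Idi1, Crat, Acaa2, Acsl5, Elovl1 and Lpin1 ended, and without batch 1 those of Cpt1a, Abca1, Abcg1, Scd1, Idi1, Acsl5 and Elovl1.

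The diet effects of the sexes, which share no libraries, were compared across genes. Over 19616 genes the log2 fold changes of females and males correlated at Pearson's r = 0.295 and Spearman's rho = 0.258; genes are not independent replicates. The jackknife SE of r over libraries was 0.168, so that r lay less than 2 SE from 0, and r ranged from 0.196 to 0.357 with single libraries left out. It lay below that range with no low-count filter and above it with the globin level as covariate. Of the 1064 genes called in females, 972 (91.4%) had the same sign in males, where their median size in the female direction was 0.27 against 0.78 in females. Car1 and Aldh1a7, the genes called in males, were lower in females too, against 0.0644 genes for independent lists of these lengths.

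No gene passed the test of a difference between the diet effects of males and females. The smallest adjusted p was 0.589 in edgeR's quasi-likelihood test, with 1633 genes at an unadjusted p under 0.05. DESeq2 called 4 genes, limma-voom 0, and edgeR with no low-count filter 572. Among the genes with the smallest p, the male minus female effect on the log2 scale was -3.32 ± 0.70 (SE) for the chemokine receptor gene Ccr8, 2.33 ± 0.50 for Vwce and 1.28 ± 0.27 for Tspan33. It was 1.66 ± 0.42 for Slc30a10 and -1.01 ± 0.27 for Serpina3g, both called in females. Within batches 1, 2 and 3 the count was 0, 0 and 253, and the greater number of genes called in females is therefore not shown to be a difference between the sexes.

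Control males and females differed in 22 genes, 17 higher and 5 lower in males (edgeR quasi-likelihood test). Besides Y-linked genes and Xist, the histone demethylase Kdm6a, which escapes X inactivation, was 1.73-fold lower in males at 52.7 ± 4.50 against 90.7 ± 4.45 CPM (mean ± SD, n = 6, edgeR adjusted p = 3.68e-06). Males had more RNA of the stem cell genes Mecom (1.69-fold, edgeR adjusted p = 0.00743) and Angpt1 (1.62-fold), of the B cell genes Fcrla (2.49-fold) and Ms4a1 (3.32-fold), of Irf1, an interferon-induced transcription factor (1.95-fold), and of Skil (1.71-fold), Bhlhe40 (1.66-fold) and Egr3 (2.51-fold). Stard10, Cldn10 and Ccdc74a were 1.77-fold, 1.76-fold and 2.74-fold lower. Mecom and Angpt1 were also called in the female diet comparison, which uses the same female control libraries.

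By list, camera called B cell genes higher in control males (15 of 15 positive, 2 past edgeR's test, 10 adjusted over the list alone; adjusted p = 2.49e-10, adjusted p = 0.0737 with an estimated correlation), interferon gamma genes higher (1 past the test, 14 adjusted over the list alone; adjusted p = 3.14e-11, adjusted p = 0.248 with an estimated correlation) and megakaryocyte-erythroid genes lower (0 past the test, 1 higher and 8 lower adjusted over the list alone; median -0.40, adjusted p = 3.75e-07, adjusted p = 0.0949 with an estimated correlation). It called 18 lists in all, the Y-linked and X-linked ones among them. Stem cell, lymphoid, mature neutrophil, mature erythroid, T and NK, mast cell, stromal, type I interferon, immediate early, hypoxia and Hox lists were called higher and the G2/M and oxidative phosphorylation lists lower. Their adjusted p-values ran from 3.14e-08 to 0.0420, and with an estimated correlation none was called (lowest adjusted p = 0.0737). Within batches 1, 2 and 3 edgeR's count was 7, 8 and 555 genes. It was 13 or 14 without female control library 3, 5 or 6, male control library 1, 3, 4 or 6, or male Western-diet library 1, 2, 3 or 6, 35 without male control library 5, 39 without male Western-diet library 5, and 107 without female control library 2. It was 9 without both female control libraries of batch 3, where none of the autosomal genes named here passed.

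Western-diet males and females differed in 16 genes, 11 higher and 5 lower in males (edgeR quasi-likelihood test). All 5 lower genes lie on the X chromosome: Xist, Kdm6a (1.64-fold), the translation factor gene Eif2s3x (1.57-fold), Pbdc1 (1.47-fold) and Tsix (4.15-fold), which overlaps Xist on the other strand and cannot be told apart from it without strand. Fosb, an immediate early transcription factor gene, was 1.97-fold higher in males (219 ± 70.2 against 112 ± 39.5 CPM, n = 6, edgeR adjusted p = 0.00797) and Bhlhe40 1.53-fold. The other autosomal genes, all higher in males and chosen after their values were seen, were Alox15 (1.23), Gm35808 (1.16) and D830036C21Rik (1.36). Their calls and that of Bhlhe40 ended in 11 to 16 of 38 other settings, with the replicate block among them. Eif2s3x and Pbdc1 lost their calls in 12 and 10 of 38, among them 8 and 6 with a single library left out. The immediate early and heat shock list, which can respond to cell handling, had a median of 0.35 (1 gene past the test, 9 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.07e-05, adjusted p = 0.148 with an estimated correlation). Within batches 1, 2 and 3 edgeR's count was 7, 13 and 102, and it was 10 without male Western-diet library 6.

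The sorted surface markers did not pass edgeR's test in any of these comparisons. Kit stood at 526 ± 79.5, 500 ± 174, 555 ± 91.0 and 564 ± 204 CPM in control females, Western-diet females, control males and Western-diet males (mean ± SD, n = 6). Ly6a, the Sca-1 gene, which has close relatives, stood at 8.49 ± 5.16, 16.1 ± 5.61, 17.1 ± 11.8 and 14.7 ± 2.49 CPM, with an edgeR adjusted p of 0.0994 for diet in females. Ly6a was thus far below Kit in every group although the cells were sorted for Sca-1. The cause was not tested, and these values do not show how pure the sorts were. Lymphoid priming genes had medians of 0.09 in females and -0.03 in males for diet (camera adjusted p = 0.431 and 0.730), and the mature neutrophil genes 0.34 and 0.08 (0.197 and 0.957). For the mast cell and basophil list camera's adjusted p was 0.0510 in females and 0.992 in males, for the dendritic cell and macrophage list 0.422 in females, for the T, NK and innate lymphoid list 0.919 in females (both lists were called lower in males), and for the stromal and endothelial list 0.778 in females and 0.992 in males. The share of reads outside annotated features was 10.98 ± 2.88% in Western-diet and 9.08 ± 0.379% in control females, and 10.9 ± 1.14% and 9.79 ± 1.85% in males. Female Western-diet library 3 had 16.4%, with 11.5% next in its group. The medians were 10.1% in Western-diet and 9.02% in control females. Protein-coding genes held 97.5 ± 0.205% and 97.8 ± 0.322% of gene counts in Western-diet and control females, and 97.5 ± 0.255% and 97.6 ± 0.238% in males. Over both sexes this share differed by -0.239 percentage points with Western diet (permutation p = 0.00767, 0.0691 adjusted over 9 library measures).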

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

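The covariate fits, the comparison of left-out pairs of female control libraries, the granulocyte-monocyte test, the count of autosomal genes and the use of split counts for the interferon and B cell lists were chosen only after the result was seen, while the tests of residual spread, of selection and of the numbers of genes and lists called in other splits were set before.

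Genes of the megakaryocyte-erythroid list were lower with maternal Western diet. Carry-over of red cell RNA that follows the globin level would shrink this once that level enters the model. Yet the median log2 fold change of the list in the average went from -0.37 to -0.49 (camera adjusted p = 5.81e-17). With the share of reads in no feature as covariate it was -0.43 (camera adjusted p = 1.27e-15). In the average this argues against that share, and against carry-over that follows globin, as the whole cause. In females Slc4a1 and Epb42 fell while the globin Hbb-bs did not pass edgeR's test. Carry-over of red cell precursors that the globin level does not track was therefore not tested. More Sca-1-negative progenitors of all kinds in the control sorts, which the gate should remove, would also carry granulocyte-monocyte genes. The score of these was instead higher with Western diet by 0.44 (permutation p = 0.00146), though 8 of 100 splits gave that list as small a camera p. RNA of Ly6a, the Sca-1 gene, was lower in control than in Western-diet females without passing edgeR's test, and was not lower in control males. These values do not settle this explanation. An excess of cells biased to the erythroid lineage alone in the control sorts was not tested. A smaller share of erythroid-primed cells and lower expression per cell may each remain, as hypotheses that RNA from whole sorted populations does not separate.

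Many genes were called for diet in females (1064) and few in males (2), while edgeR's test of the difference called 0 (1633 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom and 572 by edgeR with no low-count filter). Leaving out both female control libraries of batch 3 left 154 genes, against 1056 without the pair of batch 1 and 753 without that of batch 2, so a large part of the female count may rest on these libraries. Larger spread among male libraries is argued against. The fit shares the spread over all groups, and the median SE of a log2 fold change was 0.215 in males and 0.216 in females. The median ratio of male to female residual SD was 0.870. By group the median residual SD was 0.305 and 0.206 in control and Western-diet males, and 0.249 and 0.349 in control and Western-diet females. Choosing genes by their female p inflates female sizes: the male change of genes chosen that way was 34.4% of the female one (median), and the reverse share was 63.1%, which leaves open how much selection adds. A sex difference in the response to maternal diet stays open too.

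Interferon and B cell lists were higher with Western diet in females. At the preset correlation camera still called 3 of the 3 lists without the female control libraries of batch 3, and 3 with the share of reads in no feature as covariate. With an estimated correlation and all libraries it called none of these lists. Without that pair the medians were 0.28 for type I interferon, 0.19 for interferon gamma and 0.40 for B cell genes, against 0.50, 0.45 and 0.45 with all libraries. As small a p came from 21 (type I interferon), 28 (interferon gamma) and 14 (B cell) of 100 splits of the libraries, so a grouping unrelated to diet could give these calls, and their staying decides neither for nor against these libraries or that share as the cause. With batch 3 left out both interferon calls ended, and a response limited to that batch stays open.

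Other splits of the libraries within batch, 100 per comparison with the real one included, were fitted in the same way. For diet in females (1064 genes, highest other split 580) as many genes came from 1 split, the real one. The same held in males (2, highest other 0) and in the average (1118, highest other 6). No other split drawn thus gave such counts, and 1 in 100 is the smallest share that 100 splits can give. The splits move single libraries and may break up litters, which the labels do not name, so they cannot exclude differences between litters. For sex the totals (22 in controls and 16 in Western-diet pups, highest other 2 in both, with as many from 1 split) test nothing, since sex-linked genes alone outnumber the other splits. Of autosomal genes as many came from 1 split, the real one, in controls (14, highest other 2) and in Western-diet pups (5, highest other 2). No other split drawn gave as many autosomal genes. All 100 splits gave at least the 0 genes of the interaction (highest other 1). For the number of lists called by camera with the preset correlation chance cannot be excluded: as many came from 26 splits for diet in females (12 lists, highest other 16), 32 in males (11, highest other 17), 26 in the average (11, highest other 17), 77 for the interaction (7, highest other 16), 8 for sex in controls (18, highest other 20) and 61 in Western-diet pups (7, highest other 16).

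Single libraries lay far from the other 5 of their group in 16 of 648 groups of values tested. Chance gives 1 in 20 for independent normal values, whereas libraries of one batch share shifts and can hide each other. The test can thus miss a pair that stands apart, such as female control libraries 5 and 6. In log2 CPM, male control library 6 had the highest Ccdc74a (1.43, nearest -0.03), male control library 1 the highest Mpo (12.49, nearest 11.57) and Idi1 (5.15, nearest 4.61) and male control library 2 the highest Fosb (8.40, nearest 7.25). Male Western-diet library 3 had the lowest Igkc (5.94, nearest 6.92), Jchain (5.11, nearest 6.02) and Prdx3 (6.94, nearest 7.29). Female Western-diet library 6 had the highest Mpo (12.93, nearest 11.63) and lowest Nek2 (4.88, nearest 5.84) and D830036C21Rik (-1.59, nearest -0.57), female Western-diet library 3 the highest Galk2 (6.88, nearest 6.05), female Western-diet library 5 the lowest Sesn2 (2.97, nearest 3.82) and female control library 6 the lowest Fcer1a (-1.67, nearest -0.65). Male Western-diet library 5 had the highest Hsp90b1 (9.16, nearest 8.73). Male Western-diet library 4 had the highest score of mitochondrially encoded genes (0.56, nearest 0.10), and male Western-diet library 6 the highest share of ambiguous reads (5.20%, nearest 4.94%).

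For 7 lists camera called a difference between the male and female diet effects. The medians, male minus female, were -0.26 for stem cell genes, 0.33 for megakaryocyte-erythroid genes, -0.54 for B cell genes, -0.29 for T, NK and innate lymphoid genes, -0.58 for type I interferon genes, -0.77 for interferon gamma genes and -0.19 for hypoxia genes. None was called with an estimated correlation, where the lowest adjusted p was 0.585. The share of reads in no feature, which no gene test uses, was higher by 1.49 percentage points with maternal Western diet over both sexes (permutation p = 0.0286, 0.129 adjusted over 9 library measures). Part of this rests on female Western-diet library 3, which had the highest share of all libraries (16.4%).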

How the results depend on the processing

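The pair of female control libraries and both covariates were alternatives chosen after the data were seen, and all others were planned. The number of genes called moved with the processing in every comparison, while no called named gene changed sign in any setting. Of 66 list calls 1 reversed, the mitochondrially encoded genes between the sexes in Western-diet pups, at -0.24 with batch 2 left out against 0.29 with all batches, and the cause was not tested. Counts below are of genes called, and where no cause is given the cause was not tested.

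For diet in females (1064 genes) the count was 2023 with no low-count filter, 1805 with DESeq2, 404 with no batch term, 358 with only the 2 groups compared, 1839, 297 and 146 with batch 1, 2 and 3 left out, 154 without both female control libraries of batch 3, and 1869 with the globin level as covariate. DESeq2 kept 1049 of the 1064 genes. For diet in males (2 genes) it was 380 with no filter, 10 with a CPM of at least 1 in at least 6 libraries, 99 with DESeq2, 132 with limma-voom, 0 with no batch term, 1 with the replicate block, 1 with only the 2 groups compared, 1, 1 and 0 with batch 1, 2 and 3 left out, and 6 with the globin covariate. For the average (1118 genes) it was 1693 with no filter, 1784 with DESeq2, 466 with no batch term, 556 and 143 with batch 2 and 3 left out, 447 without the pair, and 1685 with the globin covariate. For the interaction (0 genes, edgeR; 1633 at an unadjusted p under 0.05) it was 572 with no filter, 4 with DESeq2 and 0 with limma-voom.

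Between the sexes in controls (22 genes) the count was 1296 with no filter, 276 with DESeq2, 132 with limma-voom, 8 with no batch term, 13 with the replicate block, 111 with only the 2 groups compared, 7 and 9 with batch 2 and 3 left out, 9 without the pair, 169 with the share of reads in no feature as covariate and 11 with the globin covariate. In Western-diet pups (16 genes) it was 283 with no filter, 36 with DESeq2, 10 with no batch term, 9 with only the 2 groups compared and 123 with batch 1 left out. The correlation of the female and male diet effects (0.295) was 0.0328 with no filter, where genes with few counts enter, and 0.514 with the globin covariate.

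With single libraries left out the counts ranged from 504 to 1386 in females, 1 to 13 in males, 716 to 1464 in the average, 0 to 0 for the interaction, 13 to 107 between the sexes in controls and 10 to 23 in Western-diet pups, and the correlation from 0.196 to 0.357. Of 148 calls of named genes (111 genes, some called in several comparisons), 36 stayed in every setting and 94 with each single library left out. The calls that more settings ended than kept were those of Abcg1, Cd79b, Cebpg, Ddx58, Hk2, Hoxa7, Mllt3, Parp14, Pfkp and Pgam1 for diet in females, Fcer1a, Lpin1 and Scd1 in the average, and Angpt1, Cldn10, Irf1 and Ms4a1 between the sexes in controls.

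Replicate numbers did not pair the libraries: 25 of 36 same-number pairs correlated above 0.1, but only 2 of 18 distinct values did once group and batch means were removed, which leaves the 2 libraries of a group and batch as mirror images. In 16 of 36 cases the library of the same number correlated best, against 6 by chance and 18 if the shared batch alone counted. With the replicate number as a block the counts were 827 for diet in females and 924 for the average, besides those above. Of 66 list calls by camera 8 stayed with an estimated correlation, 25 by fry, 49 with the globin covariate, 50 with batch 3 left out, 50 without the pair, 53 with no batch term, 53 with the share of reads in no feature as covariate, 54 with batch 1 and 55 with batch 2 left out, 65 with the replicate block (the B cell list for diet in males did not) and 66 with RLE size factors. Replicate number and spread limit small changes. In simulated counts at these depths, without batch shifts or correlated genes, 16 to 20% of genes changed 1.5-fold were recovered.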

Other observations

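No hypothesis was tested here; the alternative without a pair of libraries was chosen after the data were seen.

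Glycolysis genes went both ways in females with maternal Western diet. Of 25 tested, 4 rose and 2 fell (7 and 2 adjusted over the list alone). Hk2 (log2 fold change 0.65 ± 0.19 SE), Pkm (0.69 ± 0.19), Pfkp (0.69 ± 0.20) and Pgam1 (0.48 ± 0.14) were higher, and Hk1 (-0.74 ± 0.21) and Pfkm (-0.78 ± 0.15) were lower. Hk1 and Hk2 encode hexokinases, and Pfkm and Pfkp the muscle and platelet forms of phosphofructokinase; Pfkp and Pgam1 were chosen after their values were seen. Adjusted p-values from edgeR's quasi-likelihood test ran from 0.00344 for Pfkm to 0.0463 for Pfkp and Pgam1. The list was not called (camera adjusted p = 0.292), while fry's test for change in either direction gave an adjusted p of 0.00231. Fry does not compare a list with other genes, and 4183 of 19616 genes had an unadjusted p under 0.05 in edgeR's test here. In males none of the 6 passed, with Pfkm at -0.37 and Hk1 at -0.12, and edgeR called no difference between the sexes. None of the 6 passed in females without both female control libraries of batch 3. Of 38 other settings the call ended in 25 for Pgam1, 23 for Pfkp, 20 for Hk2, 17 for Hk1, 15 for Pkm and 4 for Pfkm, among them 18, 16, 12, 9, 8 and 0 with a single library left out.

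Stress genes in females also went both ways. Of 36 genes of the unfolded protein and integrated stress response the chaperone genes Hsp90b1 (0.58) and Pdia6 (0.55) rose with Cebpg (0.75), while Asns, Sesn2 and Ddit3 (-0.54) fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.292); Cebpg and Ddit3 were chosen after their values were seen. Of 39 NF-kappaB and inflammatory genes Nfkbia, Tnfaip2 (-0.79) and the chemokine gene Cxcl2 (-1.20) fell (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.190). In the cell cycle lists Cdc6 (-0.57) and E2f8 (-0.54) fell among 35 G1/S genes (3 lower adjusted over the list alone; camera adjusted p = 0.00410, adjusted p = 0.683 with an estimated correlation). Nek2 (-0.58) fell among 40 G2/M genes (0 adjusted over the list alone; camera adjusted p = 0.00773, adjusted p = 0.683 with an estimated correlation). Among 26 cholesterol genes 2 fell, among them Fdft1 (-0.63) (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00996, adjusted p = 0.683 with an estimated correlation). Cdc6, E2f8, Nek2, Fdft1, Sesn2, Ddit3, Cebpg, Hsp90b1, Pdia6 and Tnfaip2 did not pass without both female control libraries of batch 3. The calls of Cebpg and Cxcl2 ended in 26 and 17 of 38 other settings, 19 and 11 of them with a single library left out.

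In the average over both sexes, of 20 glucocorticoid response genes Fkbp5 rose (0.51) and Nfkbia (-0.45) and the metallothioneins Mt1 (-0.74) and Mt2 (-1.18) fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.644). Of 13 mast cell and basophil genes Fcer1a (0.70) and Hdc (0.45) rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.200). Fkbp5, Fcer1a and Hdc did not pass without both female control libraries of batch 3. Camera's adjusted p in the average was 0.428 for hypoxia genes, 0.493 for p53 and DNA damage genes, 0.984 for circadian clock and for fetal hematopoiesis genes, 0.676 for TGF-beta and Wnt targets and 0.186 for mitochondrially encoded genes.

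Between the sexes in Western-diet pups, oxidative phosphorylation genes were lower in males by camera (median -0.18, 73 of 76 negative, adjusted p = 4.87e-11, adjusted p = 0.925 with an estimated correlation), with 0 past edgeR's test over all genes or adjusted over the list alone. Camera called the stromal and endothelial (median 0.30, adjusted p = 0.000182), mature erythroid (0.27, 0.0368) and mitochondrially encoded lists (0.29, 0.0171; negative with batch 2 left out) higher. Each had an adjusted p = 0.925 with an estimated correlation. In control pups the mature erythroid list had a positive median in males (0.60, camera adjusted p = 0.0119, adjusted p = 0.441 with an estimated correlation) and the megakaryocyte-erythroid list a negative one (-0.40).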
